A study of Mus musculus with 1000 samples.

How the data were processed

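The series is 1 portion of a brain RNA-seq screen of mice carrying mutations induced with N-ethyl-N-nitrosourea (ENU), an alkylating mutagen. Per the labels' protocols, C57BL/6NCrl founder males received 3 doses of 100 mg/kg ENU, the mutations were bred to homozygosity, and generation 3 animals were usually sampled at 8 to 12 weeks of age. The brain was taken without the cerebellum and kept in RNAlater before RNA extraction. Libraries were made with a 3' end-counting chemistry (SMART-Seq v4 3' DE) from 4 ng of total RNA and 8 amplification cycles, per the labels' protocols. Each sample of a plate row carried its own in-line index, the 12 samples of a row were pooled after amplification, and each row pool received a separate Nextera index pair. A batch comprised 96 such pools, or 1152 libraries. The submitters' processing notes name the aligner GSNAP and the mouse build GRCm38; their versions, the read counting and the normalization are not given in the sources used here.

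The only file used here is a lookup table, deposited by the authors as a spreadsheet, with 3 columns: a row number, a library name and a text label for 1 of 3 parts of the processed data. It holds no read count, expression value, quality measure or other measurement. The design text of the series says that the processed data of these samples are held in another series, which was not used here. Expression was therefore not analysed here, sequencing depth is unknown, and no gene, fold change, interval or detection limit is given. Gene lists for microglia, astrocytes, interferon response and other brain and blood cell types were fixed before the data were examined, together with a permutation test between ENU numbers; neither was used. The reference annotation was not used either.

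All 1000 samples carry the tissue label whole brain and the same value of the only other characteristic, so they form 1 group, and no comparison between groups was made. The table was read with pandas 2.3.3 under Python 3.11.15, and the map of positions was drawn with matplotlib 3.10.9. A sample was matched to a table entry by its exact title. Each library name was split into its parts: the number after "ENU", the number after "G3", a row letter with a column number, the number after "neuro", and the number after "S". The labels do not define these parts, and they are called here by the text they follow. A further number at the end of each name was not used in the counts. The row letter and column number were read as a plate position and the neuro number as a plate. This reading was checked on the table: on the 16 neuro numbers of the series the table lists 1536 libraries at 1536 distinct positions. A row letter within a neuro number is called a row pool below, and each of the 85 row pools of the series carries 1 S number. Names elsewhere in the table were used only to count libraries; 23053 of the 23231 names follow the pattern of the series' titles, and the other 178 were left out of counts by position. Alternatives were matching without regard to case and blanks, matching by the library name in the sample description, counting all libraries of the table in place of those of the series, and keeping ENU numbers with at least 6 libraries.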

Results

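The study screened the brain transcriptomes of many mice descended from ENU-treated founders to find animals with abnormal inflammatory states and then sought their causal variants by exome sequencing. This portion comprised 1000 libraries all labelled whole brain, although the protocol describes brain with the cerebellum removed. The labels give 1 kind of sample, with no control group or treated group. The file used here assigned libraries to parts of the processed data and held no expression values; the design text places the processed data of these samples in another series, which was not used here. No inflammatory gene, cell type marker or affected animal was therefore measured here, and what follows describes how the libraries were arranged.

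The lookup table listed 23231 libraries under 23231 distinct names. All 1000 samples of the series were found in it by exact title, which is 4.30% of its entries. They occupied entries 22001 to 23000 without a gap. All 1000 were assigned to the third of the 3 parts, of which they made up 12.9%. The parts were of nearly equal size, with 7743, 7743 and 7745 libraries.

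The 1000 libraries carried 90 different ENU numbers, with a mean of 11.1 ± 2.20 libraries per number (SD over the 90 numbers) and a median of 12. There were 77 ENU numbers with 12 libraries and 11 with 6 libraries. The remaining 2 had 7 and 3 libraries. The protocol states that 12 siblings of a pedigree were typically screened; the labels do not state that the ENU number is the pedigree. The numbers after "G3" ran from 1 to 34, and each combination of ENU number and G3 number occurred once, giving 1000 distinct combinations. None of these combinations was listed a second time among the 23053 names of the table that follow the pattern of the titles; the remaining names were not split into these parts.

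The libraries were spread over 16 neuro numbers, with between 12 and 96 libraries on each and a median of 63. On 5 of the 16, all 96 positions belonged to the series. A set of 12 consecutive neuro numbers held 92.1% of the libraries. The other 79 libraries lay on 4 lower neuro numbers. Within each of these sets the S numbers followed a single rule, rising by 1 per row letter and by 8 per unit of neuro number. The rule was read from rows of the series only. On the 4 lower neuro numbers few rows belonged to the series, so most single steps were not observed there. The 12 column numbers were used almost evenly, by 82 to 85 libraries each. This range is fixed by the row pools, because 82 of the 85 had all 12 columns filled by the series.

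ENU numbers were not spread over plates or rows. The libraries of each of the 90 ENU numbers lay on 1 neuro number and in 1 row pool. The series touched 85 row pools, of which 82 held 12 libraries of the series. With every library of the table counted, all 85 row pools held 12 libraries, 79 of them with a single ENU number and 6 with a pair. Thus 93.4% of the 1000 libraries were pooled only with libraries of their own ENU number, and 6.6%, or 66 libraries, shared their row pool with those of another ENU number.

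**Figure D1:**
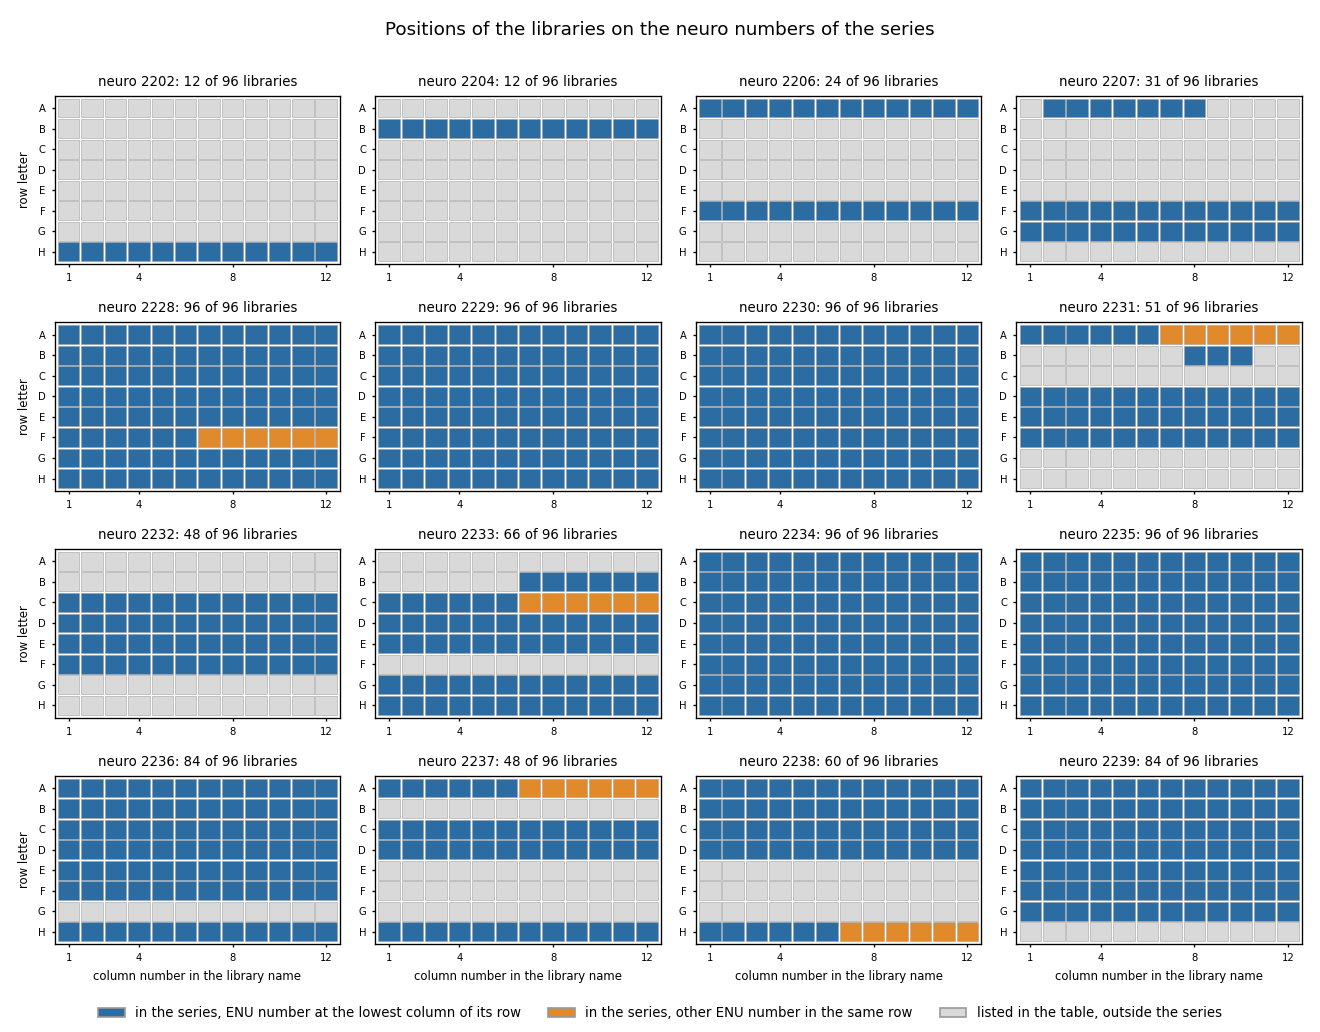
Each panel is 1 of the 16 neuro numbers, with the row letter on the vertical axis and the column number on the horizontal axis; each square is 1 library, blue or orange where it belongs to the series (orange marks the ENU number further along a row that holds a pair) and grey where the table lists it outside the series. Most rows are of a single colour from end to end, and 5 rows hold a pair of ENU numbers from the series. Grey does not show the ENU number, and a change between grey and another colour within a row marks only the edge of the series.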

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

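All 1000 samples were found in the lookup table by exact title and by the library name in the description (100% each). Matching by title without regard to case and blanks also gave 100%. It relaxes the exact match and so could not have found fewer. Counting all libraries of the table in place of those of the series raised the number of neuro numbers with 96 libraries from 5 to 16, because the table also lists libraries outside the series on the same plates. The same change raised the number of ENU numbers with 12 libraries from 77 to 79, since 14 libraries of 2 ENU numbers lie outside the series. Keeping ENU numbers with at least 6 libraries left 89 of the 90, each on 1 neuro number. This outcome was fixed in advance, because all 90 already lay on 1 neuro number each. Alternatives chosen before the data were examined for a measurement per library (untransformed values, and centring on neuro number and row) were not run, because the table holds no measurement. Leaving out replicates, other normalizations and filters on low values do not apply for the same reason.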

Other observations

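These observations were made after the table was examined. The row is the unit in which cDNAs were pooled and given an index pair, and every ENU number of the series lay in 1 row pool. For the 93.4% of libraries in row pools with a single ENU number, ENU number and row pool coincide. A difference between these ENU numbers in any expression readout would also be a difference between row pools. The 2 cannot be told apart from these libraries by position alone. ENU numbers on different neuro numbers differed in plate as well, and some also differed in the set of neuro numbers described above. The S numbers of the 2 sets overlapped (56 to 95 and 1 to 95). The 16 neuro numbers hold 1536 listed libraries, more than the 1152 of 1 batch of the protocol. With each neuro number read as a plate, the 16 therefore cannot all belong to 1 batch. If an S number stands for 1 pool of a batch, the overlap places the 2 sets in different batches. The labels do not define the S number, and this division was not examined further. Within the series, 5 row pools held a pair of its ENU numbers, with 60 libraries. In all 5, 1 ENU number filled columns 1 to 6 and the other columns 7 to 12, so within these pools the ENU number coincided with the block of columns, and with it the set of in-line indices if these follow the columns. In the other mixed row pool the partner ENU number lay wholly outside the series. Differences between libraries of 1 ENU number lie within a pool and are free of the overlap with the row pool only. Each such library still had its own column and, per the protocols, its own in-line index. A difference between libraries therefore coincides with a difference in position and index. Row pools with a single ENU number were not particular to the series, where they made up 79 of the 85. Whether ENU numbers outside the series were each confined to 1 row pool was not examined. Over the whole table, row pools were counted by neuro number, row letter and also S number. This added key can only lower the number of ENU numbers per pool. Of the 1925 row pools so counted, 1775 (92.2%) held a single ENU number, and the most mixed held 12.

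The boundary of the series cut across ENU numbers. The series was an unbroken run of 1000 entries, and 2 ENU numbers had 14 further libraries listed outside it. Of these, 5 belonged to the ENU number with 7 libraries in the series and 9 to the one with 3. With those libraries each of the 2 reaches 12. For 59 of the 90 ENU numbers the G3 number rose at every step along the row as the column number rose.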
